A study of Oncorhynchus mykiss with 18 samples.

How the data were processed

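Gene expression was measured on 18 custom 1-colour oligonucleotide arrays of rainbow trout (Oncorhynchus mykiss) testis sequences. Per the labels' protocols, cells of immature male testis were stained with the DNA dye Hoechst 33342 and sorted by flow cytometry into side population (SP) cells, which hold little dye, and non-SP cells. Total RNA was purified with a column kit that includes DNase digestion, and 25 ng of RNA was labelled with Cy3, per the labels' protocols. The labels give 9 SP and 9 non-SP samples, 1 of each from every combination of 3 parental fish groups and 3 collections. The 2 samples of a pair share a fish group and a collection and lay on 1 slide. Collection 1 makes up scan batch 1, with 3 pairs, and collections 2 and 3 make up scan batch 2, with 6 pairs. The labels do not say how many fish entered a pool, so the p-values measure the spread between these samples.

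The deposited scanner files hold intensity values that were extracted from images of a GenePix 4000B scanner at 5 µm per pixel with Feature Extraction version 9.5.3.1, per the file headers. The submitters' processing notes name Agilent Feature Extraction 9.5. Each array was scanned at 2 gains, so that 36 scans were read. The processed intensity of each spot had been background-subtracted, spatially and multiplicatively detrended, and replaced by a surrogate value where it was close to background, per the file headers. Other deposited columns used here are 0 or 1 flags for spots well above background, saturated spots and outlier spots. The authors' deposited series table holds log2 values whose scale, centring and direction are not given in the sources used here. Set against the scanner files, its columns had the rank order of the processed intensity of the brighter scan and a common distribution, with column medians of 6.82 in every sample, so the values are log2 and quantile normalized. In that table, 28260 rows, which are 26.9% of all rows, carried the value of the feature with the number 1 lower. Spearman's rho with the scanner values at the same number was 0.0153 at most in these rows, and it was 1.0 after the shift was undone. The shift was undone before the table was used as an alternative, and the table with rows at their deposited numbers was kept as a further alternative chosen after seeing the data.

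Each array holds 103747 non-control spots of 55928 probes of 60 bases. Of these probes, 28587 carry the identifier of an assembled contig and 27340 that of a single sequencing read. The files pair no identifier with a gene name, give every probe the description unknown and list every position as unmapped. A reference table of 72772 rainbow trout genes (assembly USDA_OmykA_1.1) held 0 of the identifiers, and no genome was used here. Gene list tests, cell type markers, named transporters and the alternative with 1 probe per named gene, all planned before the data were examined, therefore could not be run. The planned rule for named genes asked for a gene name, the same direction in all 9 pairs and the largest log2 difference at an adjusted p under 0.05. It was applied without the name, and at most 2 identifiers are printed per direction or per comparison, with their probe sequences. For the other comparisons the probes with the largest range between the 3 level means were taken.

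The log2 processed intensity of each spot was expressed relative to the 75th percentile of the non-control spots of its scan. Outlier spots were left out, the spots of a probe were averaged, and the 2 scans of an array were averaged to 1 value. A probe counted as detected on an array when at least 50% of its spots were well above background in either scan. The 38471 probes detected on at least 5 of the 9 arrays of SP or of non-SP were tested, which is 68.8% of all probes. SP and non-SP were compared with limma 3.58.1 in R 4.3.3 (lmFit, empirical Bayes moderation), with fish group as covariate, two-sided, with Benjamini-Hochberg adjustment and a threshold of adjusted p 0.05. Differences between fish groups and between collections were tested with limma's moderated F test on the mean of each pair, and differences in the SP effect with the same test on the SP minus non-SP difference of each pair, each with the other factor as covariate. Array measures were compared by exact two-sided sign-flip permutation over the 9 pairs (512 sign patterns, smallest possible p 0.00391). Where a probe was not well above background on any array of a group, its fold is given as a bound against the mean of the higher of its own signal and the lowest signal of any detected probe on each array, with the adjusted p of the fit. The same raised values were used, after seeing the data, for 2 probes well above background on 1 SP array. The lowest detected signal of an array is not a detection limit, since signals not well above background can lie above it. Folds against raised values can therefore be too large. Files were read with the R package data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9.

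The replicate names pair the samples, since both cell types of a pair came from the same fish group and collection. The correlation over probes of the deviations from the group means was between 0.45 and 0.67 for the 9 pairs, and in 9 of 9 pairs it was higher than with any non-SP sample of another pair. No 2 samples of a group held the same values. The smallest SD over probes of the difference between any 2 samples of a group was 0.34 on the log2 scale. The SD between copies of a probe within a scan was 0.24, but it describes single spots and not a difference of 2 values. Set side by side, the 2 SDs therefore do not show whether samples differed beyond the noise of spots. The number of arrays limits the precision of all values.

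The fits were tested on simulated data for 38369 probes with complete values, with 50 probes changed at each of 4 sizes. In the simulated SP vs non-SP comparison, 44% of probes changed by 0.5 on the log2 scale were recovered, 82% of those changed by 1 and 100% of those changed by 2, and 10 of 169 calls were false. In the simulated test of the SP effect by fish group, 48% of probes changed by 1 in fish group 3 and 98% of those changed by 2 were recovered. In that of the SP effect by collection these shares were 66% and 96%. In the simulated fish group difference, 98% of probes changed by 1 were recovered, and in the simulated collection difference 96%. In the simulated SP vs non-SP comparison noise was drawn independently for each array, while the 2 samples of a real pair correlated. Far fewer probes were changed in each simulation than were called between SP and non-SP in the real data. The shares recovered and the false calls are therefore not those of the real fits.

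Alternatives fixed before the data were examined were the pair as a fixed or random replicate block, other covariates, each scan batch alone, each gain alone, normexp background correction (offset 50) of the mean and background signals, quantile and median scaling, other filters, the series table, array weights, a variance trend, and leaving out each pair, fish group and collection. Scaling by spike-in controls, without and with the pair as block, and 1 probe per contig stem were added after seeing the data. Spike-in levels were taken as the median over the 3 control probes that were well above background on all spots of all scans, each set to 0 at its own mean over the 18 arrays, because probes of unlike dose would otherwise leave the same probe as the median on nearly every array.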

Results

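The transcriptome of SP cells was compared with that of non-SP cells sorted from the testis of immature male rainbow trout. SP cells are defined by the export of Hoechst 33342, a property used in other tissues to enrich for stem cells. The data comprise 18 arrays, 9 of SP and 9 of non-SP cells, in 9 pairs from 3 parental fish groups sampled in 3 collections. In the brighter scans of scan batch 1 the 75th percentile of spot intensity was between 713.1 and 1019 units, and in those of scan batch 2 it was between 241.2 and 442.1 units. Between 61.1% and 74.7% of spots were well above background in the brighter scans, against at most 2.33% of negative control spots. Between 32691 and 40394 of 55928 probes were detected per array. Correlations over probes between replicates were between 0.95 and 0.99 in SP and between 0.94 and 0.98 in non-SP.

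The first question was how SP and non-SP cells differ in expression once parental fish group is taken into account. Of 38471 probes tested, 20715 differed between SP and non-SP, with 10803 higher and 9912 lower in SP. Among these, 1909 were at least 2-fold higher in SP and 1089 at least 2-fold lower, against 1409 and 1479 after median scaling and 33 and 131 after normexp background correction, which adds an offset of 50 to every signal. Differences beyond 4-fold were fewer, with 30 probes higher and 57 lower. The direction was the same in all 9 pairs for 14531 of the called probes, and 41.5% of tested probes had 1 direction in all pairs where chance gives 0.391%. Some probes passed the detection rule in 1 cell type alone. There were 69 tested probes detected on all 9 SP arrays and on 0 of the 9 non-SP arrays, and 4 with the opposite pattern. SP arrays also had more spots well above background (70.3% against 66.1%). These 2 counts therefore do not separate cell type from the overall signal of the arrays. The cell types lay apart on the first principal component, which held 41.9% of the variance.

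**Figure D1:**
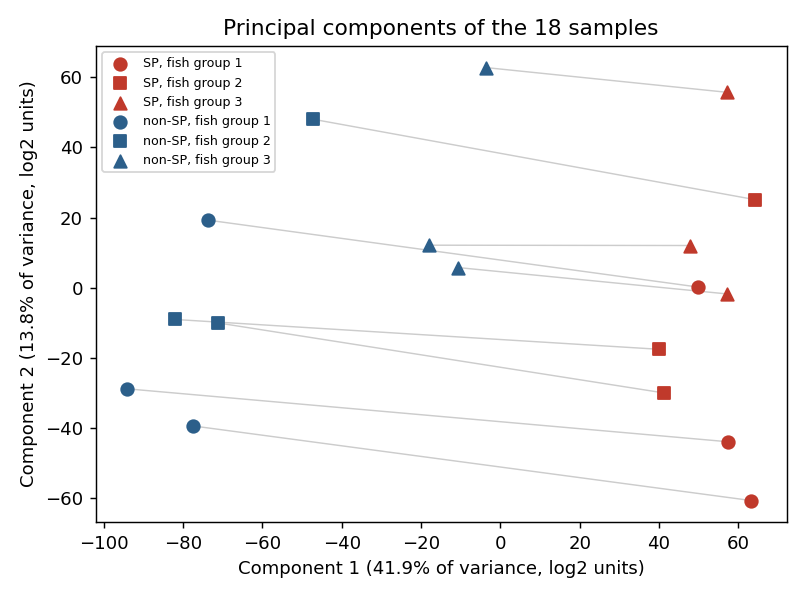
First 2 principal components of the 18 samples over tested probes, in log2 units, with cell type in colour, fish group as the marker and grey lines joining the 2 samples of a pair. SP samples lie at positive values of component 1 and non-SP samples at negative values, and the non-SP samples of fish group 3 average -10.8 where those of fish group 1 average -81.8.

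The 2 probes with the largest fitted rise in SP were detected on all 9 SP arrays and not well above background on any non-SP array. The probe of contig YGL02.17089.C1 (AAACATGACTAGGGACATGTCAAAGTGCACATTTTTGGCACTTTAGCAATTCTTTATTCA) had a level of -2.35 ± 0.96 in SP and -5.19 ± 0.35 in non-SP (log2 relative to the 75th percentile, SD, n = 9), which is at least 5.83-fold higher in SP (adjusted p = 6.80e-07, higher in 9 of 9 pairs). The probe of read YGL02_GNYA1SO04JRA5M (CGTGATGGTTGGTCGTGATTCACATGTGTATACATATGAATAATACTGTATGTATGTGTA) was at -2.70 ± 0.32 in SP and -5.20 ± 0.50 in non-SP (SD, n = 9), at least 4.47-fold higher in SP (adjusted p = 6.48e-08, 9 of 9 pairs). Both bounds, and the rank of these probes, hold for the background-subtracted signal. They rest on the lowest detected signals of the arrays, -5.97 to -4.51, which are not a detection limit. In the non-SP sample of Group3-3rd, YGL02_GNYA1SO04JRA5M was at -3.95 and not well above background. After normexp correction, the log2 differences of YGL02.17089.C1 and YGL02_GNYA1SO04JRA5M were 0.65 and 0.41.

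The 2 probes with the largest fitted fall were detected on all 9 non-SP arrays. The probe of contig YGL02.5735.C1 (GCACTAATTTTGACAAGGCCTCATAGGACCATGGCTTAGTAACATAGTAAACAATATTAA) fell from -1.32 ± 1.34 in non-SP to -4.98 ± 0.40 in SP (SD, n = 9), a fitted difference of -3.66 ± 0.32 (SE) on the log2 scale (adjusted p = 1.86e-07, lower in SP in 9 of 9 pairs). It was well above background on 1 of the 9 SP arrays, so that this size rests on signals near background. With SP signals below the lowest detected signal of their array raised to it, YGL02.5735.C1 differed by -3.64 ± 1.37 (SD, n = 9), and after normexp correction by -1.35. The probe of read YGL02_GNYA1SO04H5GAY (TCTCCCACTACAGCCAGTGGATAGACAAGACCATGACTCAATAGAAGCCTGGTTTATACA) fell from 0.44 ± 1.32 to -3.15 ± 0.73 (SD, n = 9), a difference of -3.59 ± 0.37 (SE, adjusted p = 1.06e-06, 9 of 9 pairs), and was well above background on 7 of the 9 SP arrays. In both, the non-SP level was highest in fish group 1.

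**Figure D2:**
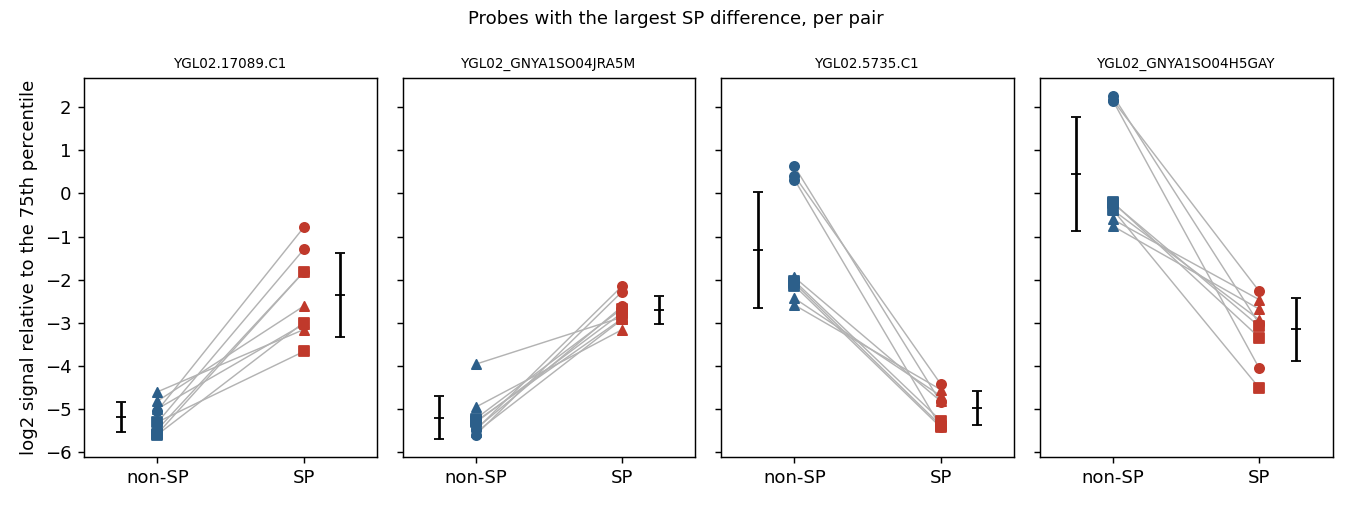
Level of the 2 probes with the largest fitted rise and the 2 with the largest fitted fall in SP, as log2 signal relative to the 75th percentile, with lines joining the samples of a pair, and markers for fish groups 1 (circle), 2 (square) and 3 (triangle), and black bars for mean and SD (n = 9). Each pair moves in the direction of the group means in all 4 probes, and the non-SP signals of the 2 higher probes and 8 of the 9 SP signals of YGL02.5735.C1 are not well above background.

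Probes of contigs with like names moved together. Contig identifiers were grouped by the stem of their name, the part before the last point, whose meaning the files do not give, and in 1075 of the 1185 stems with at least 2 called probes all called probes had the same direction. This is 90.7%, against 44.6% on average and 49.0% at most in 1000 shuffles of the calls among contig probes. Of the 104 stems with at least 5 tested probes, 28 had at least 80% of their probes lower in SP and 4 had at least 80% higher. Called probes made up 57.6% of contig probes and 49.1% of read probes. Higher calls were 55.3% of the calls among contig probes and 47.5% among read probes. The median level was -0.89 in contig probes and -1.34 in read probes. Neither signal level nor the number of spots per probe was matched between these 2 kinds.

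On values scaled to the 75th percentile, the direction of the difference went with the signal level. In the dimmest sixth of tested probes the median SP minus non-SP difference was 0.26 on the log2 scale, with 2529 probes higher and 1004 lower, and the median was above 0 in 9 of 9 pairs. In the brightest sixth it was -0.17, with 724 higher and 2721 lower, and the median was below 0 in every pair. The brightest minus the dimmest sixth was -0.43, against -0.14 after quantile normalization and -0.006 after normexp background correction, where the trend was absent and both ends lay low, at -0.10 and -0.09. The brightest sixth was at 0.00 after quantile normalization and at 0.41 after spike-in scaling, which raises the median of all probes to 0.58.

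**Figure D3:**
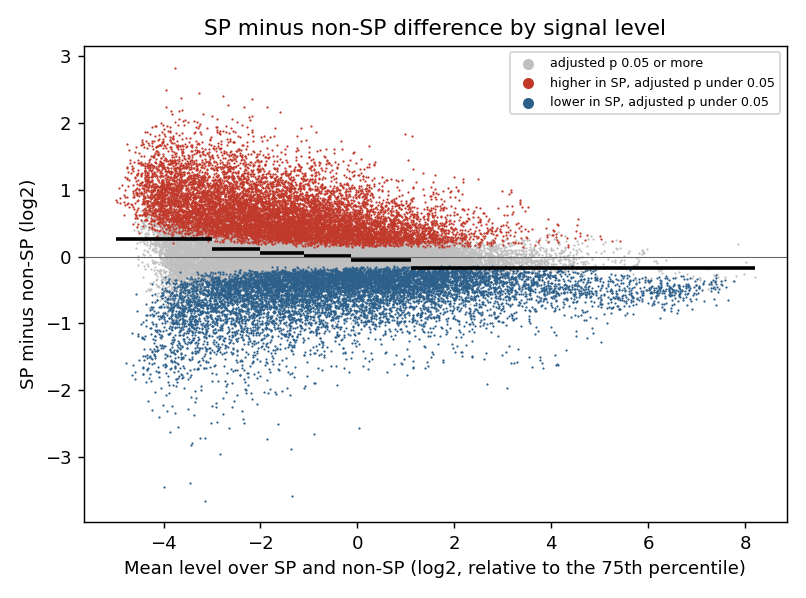
SP minus non-SP difference (log2) of each tested probe against its mean level (log2 relative to the 75th percentile), with probes past adjusted p 0.05 in colour and black lines for the median in 6 classes of equal size. The class medians fall from 0.26 at the dim end to -0.17 at the bright end, while after normexp correction the dimmest class is at -0.09 and the brightest at -0.10, and after spike-in scaling they are at 0.84 and 0.41.

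These calls rest on limma's moderated test with fish group as covariate, on values scaled to the 75th percentile. With the pair, which is also the slide, as a block 25171 probes were called (12499 higher, 12672 lower), with scan batch added 23138, in scan batch 1 alone 6943 and in scan batch 2 alone 18688, and 99.6% of probes called in batch 1 had the same sign in batch 2, 98.6% the other way round and 87.8% among all tested probes. The balance of higher and lower calls depends on the scaling, with 8671 higher and 12643 lower after median scaling, 4984 and 8168 after normexp background correction, and, added after seeing the data, 5168 and 109 after scaling by spike-in controls, or 29025 and 1625 with the pair as a block, where 2109 probes had the opposite direction to their call above.

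The arrays of the 2 cell types differed in overall signal as well. The log2 75th percentile of intensity was 7.89 ± 0.54 in SP and 7.61 ± 0.69 in non-SP (SD, n = 9), higher in SP in 7 of 9 pairs (exact sign-flip permutation p = 0.0156, adjusted p = 0.0156 over 3 measures). It differed by 0.41 ± 0.16 in the 6 pairs of scan batch 2 and by 0.04 ± 0.13 in the 3 pairs of scan batch 1. The share of spots well above background was 70.3% ± 3.5 in SP and 66.1% ± 2.3 in non-SP (SD, n = 9, exact p = 0.0117, adjusted p = 0.0156), higher in 8 of 9 pairs, with differences of 2.83 ± 2.68 points in scan batch 1 and 4.91 ± 3.86 in scan batch 2. Saturated spots made up 0.137% ± 0.151 in SP and 0.186% ± 0.216 in non-SP (SD, n = 9, exact p = 0.0156, adjusted p = 0.0156), with a higher share in SP in 2 of 9 pairs. That difference was -0.14 ± 0.02 points in scan batch 1 and -0.00546 ± 0.00590 in scan batch 2, and in the dimmer scans it was -0.00568 (exact p = 0.25).

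The series was designed so that effects of parental fish could be set apart. Over the mean of each pair, 15256 probes differed between the 3 fish groups, 39.7% of those tested, and 1760 of them had a range of at least 2-fold between fish groups. The largest ranges came from probes with little or no signal above background in 1 fish group. The probe of contig YGL02.3333.C1 (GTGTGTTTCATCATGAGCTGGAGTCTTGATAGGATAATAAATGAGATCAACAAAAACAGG) was at 3.75 ± 0.36 in fish group 1 and 3.60 ± 0.10 in fish group 3 (SD, n = 6), and was not well above background on any of the 6 arrays of fish group 2, so that fish group 1 was at least 496-fold higher (adjusted p = 1.32e-07). The probe of contig YGL02.1551.C2 (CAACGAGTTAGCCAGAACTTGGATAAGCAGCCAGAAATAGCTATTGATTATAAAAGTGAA) was at 1.45 ± 0.35 in fish group 2, 0.10 ± 0.51 in fish group 3 and -5.20 ± 0.74 in fish group 1 (SD, n = 6, adjusted p = 4.38e-05), where 1 of 6 arrays was well above background. Both probes showed this in SP and in non-SP arrays. The fold of YGL02.3333.C1 is against raised signals of fish group 2 and not against a detection limit. Across all probes, 84 were detected on all 6 arrays of 1 fish group and on 0 of the other 12, or on 0 arrays of 1 fish group and on all 12 others. For collections there were 13 such probes, and other divisions of the 9 pairs into 3, 3 and 3 gave at most 36. The fish group count was 8603 without pair Group3-3rd, 9112 without Group3-1st and 10109 without Group1-3rd, and 4652 when collection was not in the model.

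Between the 3 collections 15634 probes differed, 40.6% of those tested, and 1388 had a range of at least 2-fold. The pair of collections 1 and 2 differed in 13376 probes, collections 1 and 3 in 7969 and collections 2 and 3 in 7291, and at 2-fold these counts were 753, 991 and 132. Scan batch 1 is collection 1, so that collection and scan batch cannot be told apart there, while collections 2 and 3 share a batch. The probe of read YGL02_GNYA1SO04H60PZ (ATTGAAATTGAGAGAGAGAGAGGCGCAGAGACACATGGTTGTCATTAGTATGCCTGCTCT) was at -2.85 ± 0.36 in collection 1, 0.22 ± 0.66 in collection 2 and -0.57 ± 0.30 in collection 3 (pair means, SD, n = 3, adjusted p = 0.00176). The probe of read YGL02_GNYA1SO04IDETQ (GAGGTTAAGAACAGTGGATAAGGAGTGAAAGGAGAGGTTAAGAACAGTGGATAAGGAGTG) was at -1.78 ± 0.59, 1.05 ± 0.14 and 1.29 ± 0.65 (pair means, SD, n = 3, adjusted p = 0.00176). The sequences of both these probes hold repeats, a GA run in the first and a repeated longer stretch in the second. Cross-hybridisation to them was not tested. The collection count was 9955 without pair Group3-1st and 4383 when fish group was not in the model. Over all probes the sum of squares divided into 36.2% for cell type, 23.8% for fish group, 19.6% for collection, 7.65% for cell type by fish group, 2.46% for cell type by collection, 6.42% for fish group by collection and 3.97% for the remainder.

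Whether parental fish group alters the SP difference itself was tested on the 9 pair differences. In fish group 3 the difference between SP and non-SP was smaller than in the other fish groups. The SD over probes of the SP minus non-SP difference was 0.77 ± 0.06 in fish group 1, 0.66 ± 0.01 in fish group 2 and 0.49 ± 0.01 in fish group 3 (SD, n = 3), and 1 of the 280 divisions of the 9 pairs, the real one, gave as large a spread between groups (exact permutation p = 0.00357, adjusted p = 0.00714 over 2 factors). By collection the values were 0.61 ± 0.11, 0.64 ± 0.14 and 0.66 ± 0.17 (exact permutation p = 0.925). These tests of the SD over probes were not among the planned comparisons. Fish group 3 also had the closest shares of spots well above background in SP and non-SP (brighter scans). In collections 1, 2 and 3 they were 66.6% and 66.3%, 63.8% and 65.5%, and 71.3% and 68.9%. In fish group 1 they were 73.8% and 68.2%, 74.7% and 67.2%, and 72.8% and 65.5%. In fish group 2 they were 69.9% and 67.4%, 69.4% and 61.1%, and 70.7% and 65.1%. A link was not tested. Of 8317 probes whose SP difference varied with fish group, 4695 (56.5%) had the same direction and a smaller size in fish group 3 than on average in the other fish groups, 3260 had the opposite direction and 362 a larger size. Of the 5793 that were also called between SP and non-SP, 4534 (78.3%) had a smaller size in the same direction and 1076 the opposite direction. That call uses all 9 pairs, fish group 3 included, so it selects against opposite directions and raises this share. Between fish groups 1 and 2, 0 probes differed in their SP effect by limma at adjusted p 0.05 and 5685 had an unadjusted p under 0.05. Between fish groups 1 and 3, 11594 differed at adjusted p 0.05, and between 2 and 3, 4452.

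The largest range of fitted differences between fish groups was in the probe of read YGL02_GNYA1SO04JFK2N (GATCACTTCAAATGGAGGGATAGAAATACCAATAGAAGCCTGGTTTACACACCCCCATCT). It was lower in SP by -5.77 ± 0.18 in fish group 1, -2.04 ± 1.76 in fish group 2 and -2.38 ± 0.42 in fish group 3 (log2, SD, n = 3, adjusted p = 0.0315). Only 1 of 9 SP arrays was well above background. With SP signals below the lowest detected signal of their array raised to it, the probe was 40.0-fold lower in fish group 1 and 5.19-fold lower in fish group 3. In fish group 3 the difference stayed at -2.38, so 5.19 is the measured ratio and not a bound. In fish group 2 the SP sample of Group2-3rd was at -2.67, where the other 8 SP samples were between -6.21 and -4.76. YGL02_GNYA1SO04H5GAY, well above background on 7 of 9 SP arrays, followed, with differences of -5.31 ± 0.89, -3.37 ± 0.67 and -2.11 ± 0.38 (SD, n = 3, adjusted p = 0.0154). The count of 8317 depended on single pairs. It was 187 without Group3-3rd, 982 without Group3-2nd, 1461 without Group1-2nd, 1854 without Group3-1st, 2168 without Group1-3rd and 4747 without Group2-3rd, and it was 3024 with the dimmer scans alone.

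**Figure D4:**
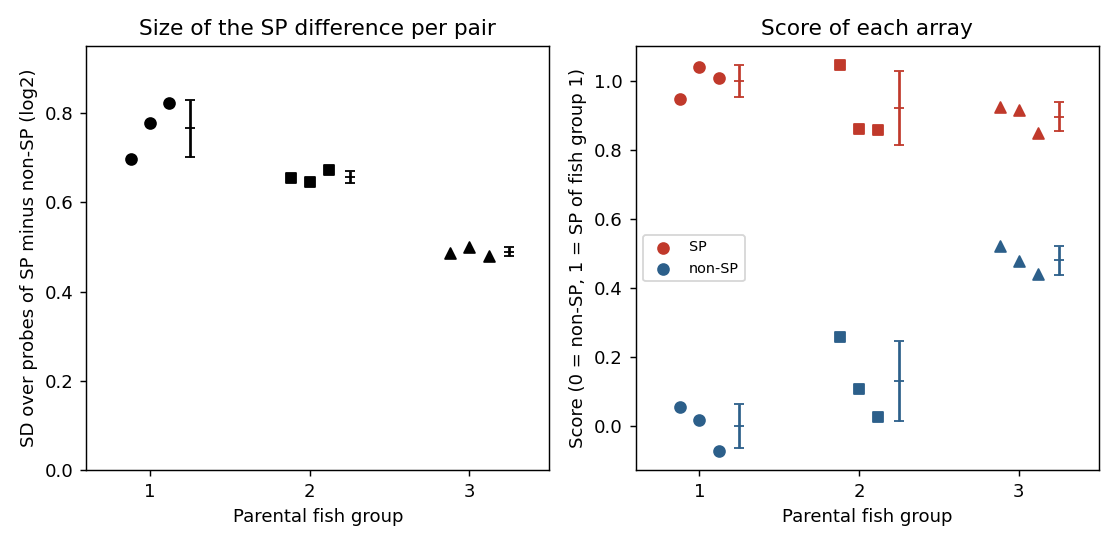
Left, the SD over probes of the SP minus non-SP difference (log2) of each pair by fish group. Right, a score of each array over probes with a 2-fold or larger difference in fish group 1, with non-SP of fish group 1 at 0 and SP of fish group 1 at 1. Points are pairs or arrays, bars are mean and SD (n = 3), and in fish group 3 the non-SP arrays average 0.48 and the SP arrays 0.90.

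The SP effect did not vary detectably with collection. By limma's moderated F test 0 probes passed adjusted p 0.05 and 3331 had an unadjusted p under 0.05, where chance gives 1924. The smallest adjusted p was 0.48.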

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

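All tests of explanations for the size of the SP difference in fish group 3 and for the trend with signal level, and the tests of spike-in levels, were chosen after the results were seen. The tests of the SD over probes by fish group and by collection were not planned either. The counts over other divisions of the samples followed a fixed procedure.

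The SP difference differed between fish groups in 8317 probes, and its SD over probes was 0.489 in fish group 3, where each pair lay below each pair of the other fish groups, also after quantile normalization or normexp correction, in either scan alone and in the series table. On a score set to 0 and 1 by the non-SP and SP arrays of fish group 1, SP arrays of fish group 3 lay -0.025 from those of fish group 2, while the non-SP arrays rose from 0.13 ± 0.12 to 0.48 ± 0.04 (SD, n = 3), which argues against non-SP cells in the SP sort. The step between 2 spike-in probes on the arrays of fish group 3 was 1.00 times that on the other arrays, while the SP difference was 0.69 times that of the other fish groups. This argues against a narrower signal range between the levels of these probes, 2.94 and -0.04. The step did not cover lower levels, where many tested probes lie. SP-type cells in the non-SP sort are a candidate explanation that stays open for the smaller size of the difference. Mixing alone shrinks a difference and does not reverse it. It would not account for the 3260 of 8317 probes with the opposite direction in fish group 3, whose reversal was not tested against its spread. A true difference of the non-SP cells with parentage also stays open and was not tested. The share of SP-type cells needed was 0.62 ± 0.03 from probes lower in SP and 0.56 ± 0.03 from probes higher in SP (SD, n = 3). These shares differ by 0.0652 ± 0.0067, so the first criterion, equal shares within the spread over pairs, would have excluded a mixture, and it was replaced after that result was seen, because fish group 2 showed an offset of 0.0943 ± 0.0555 as well.

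Spike-in control probes, which carry no trout sequence and were not compared themselves in the report, where they serve as an alternative scaling, were lower in SP by -0.58 ± 0.31 (log2 relative to the 75th percentile of trout probes, SD, n = 9), in 9 of 9 pairs (exact sign-flip permutation p = 0.00391, the smallest possible). The difference was -0.64 ± 0.30 in the 3 pairs of scan batch 1 and -0.55 ± 0.33 in the 6 pairs of scan batch 2, and by fish group it was -0.92 ± 0.06, -0.53 ± 0.24 and -0.29 ± 0.10 (SD, n = 3). Trout signal was thus 1.49-fold higher in SP relative to these controls. The amount added per sample is not given in the sources used here.

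Within the trend from dim to bright probes, the brightest sixth was lower in SP by a median of -0.168 in the dimmer scans after 20 probes with a saturated value were left out, against -0.168 over all of its probes, which argues against saturation. Over the span between 2 spike-in probes at 2.94 and -0.04, trout probes changed by -0.16 ± 0.03 and the spike-in probes by 0.005 ± 0.029 (SD, n = 9). The gap of 0.165 ± 0.032, seen in 9 of 9 pairs (exact sign-flip permutation p = 0.00391), argues against a compression shared by all spots at these levels. Spike-in probes at lower levels were not above background on all spots. Their SP minus non-SP differences ran from -0.06 (level -2.79) to -0.63 (level -2.32), against -0.58 and -0.59 in the 2 probes above. Lower levels therefore stay undecided. The brightest minus the dimmest sixth went from -0.43 to -0.14 after quantile normalization. It went to -0.006 after normexp correction, with -0.10 and -0.09 at the ends. The size of the trend thus depends on how background and scale are handled, but neither alternative can show its source. The normexp offset of 50 exceeds the median signal in the dimmer scans of scan batch 2, 16.1 to 32.2 units. It therefore shrinks differences of dim probes whatever their source. Quantile normalization gives all arrays the same distribution, which takes out a trend with signal level in part by construction. The treatment of background stays open as the source of the trend, and no biological explanation was tested.

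Single samples stood apart in 4 of 43 groups of 9 values, where chance gives about 2.15. In non-SP, the array of Group2-2nd had 61.1% of spots well above background, where the others had 65.1% to 68.9%. Spike-in probe n9 differed between SP and non-SP by 0.541 in Group1-2nd, where it was between -0.997 and -0.23 in the other pairs, and the median over 3 spike-in probes in that pair was -0.84. Over all pairs that probe alone gave -0.46, lower in 8 of 9. YGL02_GNYA1SO04JFK2N was at -2.67 in the SP sample of Group2-3rd and between -6.21 and -4.76 in the others. YGL02_GNYA1SO04JRA5M was at -3.95 in the non-SP sample of Group3-3rd and between -5.59 and -4.95 in the others.

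For SP vs non-SP, fish group, collection and the SP effect by fish group, no other division drawn reached the real count. With 99 other divisions per test, 1 of 100 is the smallest share that could be found. Chance assignment of samples is thus made unlikely for each count and is not excluded. For SP vs non-SP, 1 of 100 divisions of the 18 samples into 9 and 9, the real one, called as many as 20715 probes, and the highest other gave 13981. Among 100 divisions that part all 9 pairs it was also 1, and the highest other, which differed from the real one in the orientation of 1 pair, gave 15979. For the fish group difference 1 of 100 divisions of the 9 pairs gave 15256 or more. The highest other, 4383, was the division by collection, which could only be fitted without a covariate, and the fish group count fitted that way is 4652. The highest of the 98 divisions fitted with collection as covariate, as the real one was, gave 1640. For the collection difference 1 of 100 reached 15634, with 1982 as the highest other. For the SP effect by fish group 1 of 100 reached 8317, with 5873 as the highest other. For the SP effect by collection 0 probes were called, which all 100 divisions reach whatever the data, so the divisions say nothing about that count. The highest other gave 7374, and 92 of the other 99 gave 0.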

How the results depend on the processing

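The alternatives were fixed before the data were examined, except spike-in scaling without and with the pair block, the series table with rows at their deposited numbers, 1 probe per contig stem and the alternatives for array measures. With the pair as a fixed replicate block 25171 probes were called between SP and non-SP, and as a random replicate block 24731, of which 20549 and 20715 were also called, in the same direction, with fish group alone. SP vs non-SP gave 18541 to 20565 probes when 1 pair was left out. Higher calls then numbered 9728 to 10844, lower calls 8813 to 9794 and 2-fold calls 2576 to 3496. In scan batch 1 alone 6943 probes were called (3679 higher, 3264 lower) from 3 pairs, and without fish group 1 there were 13130 (7174 higher, 5956 lower, 1927 at 2-fold), with fewer samples in both. Without fish group 2 there were 14813, and without fish group 3 there were 20411, of which 4737 passed 2-fold. Each of these leaves as many samples as leaving out fish group 1, so sample number alone does not set the count. Normexp background correction gave 13152, with 4984 higher and 164 at 2-fold, and the cause was not tested. Spike-in scaling gave 5277 (5168 higher, 109 lower), all 5277 at 2-fold, and with the pair as replicate block 30650 (29025 higher, 1625 lower, 8287 at 2-fold). It raises every probe by the same amount within a pair, and the spike-in level varied by collection (-0.38, -0.72 and 1.07 in collections 1, 2 and 3), which the pair block takes out. Without a filter 16121 were lower and 11466 higher, against 9912 and 10803 with the filter. The median SP minus non-SP difference was then -0.11, against 0.002 with the filter. The probes added this way did not pass the detection rule, and the cause of the shift to lower calls was not tested. Among the 29582 probes detected on all 18 arrays, 1056 passed 2-fold. Of the 4 named SP probes, 3 kept their call in all 35 alternatives that tested them, and YGL02_GNYA1SO04JRA5M lost it in 1, the series table at its deposited numbers, with 0.23 (adjusted p = 0.136, and from 7.25e-09 to 0.136 over its alternatives). No alternative reversed the direction of these 4.

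Fish group difference: 4652 without collection in the model, 10091 with the series table at its deposited numbers, 9959 in SP alone and 16514 in non-SP alone, and 8603 to 15413 without 1 pair. Collection difference: 4383 without fish group, 10018 with that table, 9164 in SP alone and 11057 in non-SP alone, and 9955 to 13565 without 1 pair. SP effect by fish group: 3024 in the dimmer scans, 3758 without a filter, 5403 with the series table, 1736 with it at its deposited numbers, and 187 to 7412 without 1 pair. SP effect by collection stayed at 0 in all alternatives and from 0 to 0 without 1 pair. Some of these alternatives hold fewer samples, and the cause of the changes was not tested. Leaving out 1 pair, the 75th percentile differed by 0.24 to 0.33, the share well above background by 3.71 to 4.96 points and the saturated share by -0.06 to -0.04 points. In the dimmer scans the saturated share differed by -0.0057 points (exact p = 0.25). Gene list tests, their alternatives and 1 probe per named gene were not run for want of gene names. Signal over background limits how well the fold of dim probes can be stated.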

Other observations

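Of the tests below, the matched lists and the gap by fish group were fixed before their results were seen, while the pattern itself, the resampling of units, the probe families, the scalings by spike-in and the share of the brightest spots were chosen after seeing the data.

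Some probes share short sequences with many others, which makes groups of probes visible without gene names. There were 301 tested probes that carry a run of 14 bases found in at least 15 tested probes. Their median SP minus non-SP difference was -0.22 on the log2 scale, against 0.01 in the other probes, with 78 lower and 6 higher at adjusted p 0.05. In 10000 random lists matched on signal level, GC content and number of spots the median was -0.11 and the lowest -0.198. These lists draw unrelated probes, while the 301 fall into 6 units joined by a shared run or contig stem, the largest with 148 probes, so the lists vary too little. In a check added after seeing the data, each probe was set against the median of other probes in its own matching class. The median of these differences was -0.139, with an SD of 0.0749 when whole units were resampled. This is under 2 SD, so signal level, GC content and number of spots stay open. The gap to other probes was -0.30 in fish group 1, -0.24 in fish group 2 and -0.138 in fish group 3, so it did not rest on 1 fish group. The median was -0.10 after quantile normalization and 0.36 after spike-in scaling, where that of all probes was 0.58. Cross-hybridisation of many transcripts to such probes is a candidate explanation that was not tested.

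The probes with the run GAGAGAGAGAGAGA, 18 probes of 18 separate contigs or reads, had a median of -0.78, and only the run AGAGAGAGAGAGAG, the same repeat read from its next base, had a lower one with -0.82. The median of the 18 probes was below 0 in 9 of 9 pairs. It was -0.75 after quantile normalization and -0.20 after spike-in scaling, where it was below 0 in 6 of 9 pairs. With fish group as covariate 1 of them was called lower and 1 higher, and with the pair as a block 17 were called lower. They also differed between collections in 17 of 18 probes, with median levels of -0.92, 0.99 and 0.54 in collections 1, 2 and 3. The 18 probes with the run AAGAAGGGCAAATA were all called lower, with a median of -0.52. After quantile normalization that median was 0.02, and after spike-in scaling 0.06. It was -0.46 in the brighter scans alone and -0.57 in the dimmer scans alone, and saturation of these probes was not tested. They come from 12 contig stems or reads, and their differences had an SD of 0.05, so they are not 18 separate results.

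The brightest spots held a smaller share of the signal in SP. The brightest 1% of spots held 39.8% ± 3.6 of the signal of the dimmer scan in SP and 46.2% ± 4.2 in non-SP (SD, n = 9), with a lower share in SP in every one of the 9 pairs (exact sign-flip permutation p = 0.00391, adjusted p = 0.0156 over 4 array measures). The difference was -6.83 ± 2.05 points in the 3 pairs of scan batch 1 and -6.06 ± 2.65 in the 6 pairs of scan batch 2. The measure counts spots and not probes. Whether it is separate from the trend with signal level, for which the treatment of background stays open, was not tested.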
